A study of Homo sapiens with 7 samples.

How the data were processed

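RNA from 4 established colorectal cancer cell lines was compared on 7 microarrays that read 2 dyes each. On 6 arrays the RNA of cells carrying a short hairpin RNA (shRNA) against DNMT1, the maintenance DNA methyltransferase, was set against RNA of the same line carrying a non-silencing control. These 6 arrays cover DLD1, HT29 and RKO cells, each with shRNA number 49 and shRNA number 51, so each line has 2 arrays. The remaining array sets HCT116 cells with an shRNA against UHRF1, a protein that brings DNMT1 to newly copied DNA, against their own control. The title of that sample carries d14, perhaps a day, and the titles of the DNMT1 samples carry no such number. Per the labels, the knockdown RNA carried the dye Cy3 on the shRNA 49 arrays and Cy5 on the shRNA 51 arrays and on the UHRF1 array. shRNA number and dye orientation are therefore the same split of the arrays. The labels do not say that the arrays came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. In fits with an shRNA term that spread leaves out the difference between the shRNAs. The labels do not say either whether the arrays of a line shared 1 control RNA.

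The deposited values are 1 log ratio per probe and array, taken here as log2 from their range. The submitters' processing notes name limma, with no version given. The log base, background correction, normalization and direction of the ratios are not given in the sources used here. The deposited values cover 41000 probes, and cells without a ratio are blank. Array medians lay between -0.0243 (HT29, shRNA 49) and 0.0200 (RKO, shRNA 51), so the ratios were centred, by a method that stays unknown. Whether blank cells mark probes whose background-subtracted signal had no logarithm is not stated either. Many probes of an array hold exactly the same ratio as others, 34% to 37.5% of the ratios on the DNMT1 arrays and 44% on the UHRF1 array. Why is not stated, and a floor of the signal was not tested. Signal strengths were not used here, so no filter on dim probes was possible, and for arrays their number limits the precision.

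The direction was read by a rule fixed before the data were examined. DNMT1 lay below 0 on all 6 DNMT1 arrays, so their values were read as knockdown over control, which makes this direction likely and not settled by the labels. On the UHRF1 array the same reading rests on the mean of its 4 UHRF1 probes (-1.16), which disagree, at -3.10, -2.06, -0.18 and 0.68, so it is less certain. The probe at 0.68 holds a ratio that other probes share exactly. The falls of DNMT1 and UHRF1 are for this reason no independent check of the labels.

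Probes were named through the platform annotation as supplied by GEO. Of the 41000 probes, 29341 had 1 gene symbol, 33 had several and 11626 had none listed. Entrez identifiers matched 99.9% of the named probes to RefSeq genes of assembly GRCh38.p14, which was used only for names, chromosomes and neighbouring genes. No genome build is given in the sources used here, so no coordinates are printed. Log2 ratios of all probes with the same single symbol were averaged, giving 18646 genes, 7610 of them with more than 1 probe. A gene was tested when at least 5 of the 6 DNMT1 arrays had a value, which 17623 genes met and 1023 did not. Members of near-identical families (VCX, GAGE, PAGE, MAGEA, SPANX, CT45 and CTAG1 genes) can share hybridising RNA, so which copy was measured is uncertain.

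Genes were tested with limma 3.58.1 in R 4.3.3, with the data.table package (version 1.17.8). The all-lines test asks whether the mean log2 ratio differs from 0, with the shRNA as a covariate and the line as a random block, for which duplicateCorrelation estimated a correlation of 0.165. Each line's own coefficient, the F test over lines, the pairwise differences and the shRNA 51 minus shRNA 49 contrast came from a fit with 1 coefficient per line plus the shRNA. If the arrays of a line shared 1 control RNA, the test against 0 leaves out the spread of that control. Standard errors (SE) of means are those of these fits, moderated by limma. The shRNA term takes the difference between the shRNAs out of them, so they are not the SE of a plain mean. CXCL11, for example, had an SD of 2.15 over the 6 arrays and an SE of 0.24. All p-values are two-sided and adjusted by Benjamini and Hochberg, with a threshold of 0.05. A set of 26 gene lists was tested with cameraPR at a preset inter-gene correlation of 0.01. The tests with an estimated correlation and the rotation test used only the genes with a value on all 6 arrays, and the former had no block for the line. With 6 arrays the former also had few residual degrees of freedom, fewest for the differences between lines or shRNAs. It may therefore have had little power, which was not tried on simulated data. Estimated correlations lay above the preset 0.01 for several lists, such as 0.54 for metallothioneins and 0.37 for ribosomal proteins. Members that vary together make p-values under the preset too small, so list calls made only under it are uncertain. The UHRF1 array has no replicate and no test, so counts past a 2-fold change and the place of each list median among 10000 random lists of the same size are given; without signal strengths the random lists were not matched on expression. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 prepared tables and plots.

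Named genes followed a rule. It took DNMT1, DNMT3A, DNMT3B and UHRF1 always. For the all-lines test it took the 8 highest and 8 lowest genes past the threshold with 1 sign on all 6 arrays, filled up with genes that did not pass, and up to 4 members per list with the smallest p. It took up to 4 per direction within a line, 3 per line for differences between lines, and 8 per direction on the UHRF1 array plus 3 members of each list outside the central 95% of random lists. Genes named outside the rule are said to be so. The gene lists, the tests and most alternatives were chosen before the data were examined.

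The tests were tried on simulated data with 200 changed genes among the 17623. The all-lines fit recovered 31.3% of genes changed by 1 on the log2 scale, 80.6% of those changed by 2 and 98.5% of those changed by 4, with 5 false calls of 145. The fit within 1 line recovered 2.99%, 52.2% and 90.9% in the same order, with 20 false calls of 117 when the arrays of a line shared part of their spread, and 8 of 83 when they did not. The F test over lines recovered 0%, 1.49% and 62.1%, and the shRNA contrast 0%, 23.9% and 92.4%. The list test called the 1 planted list and 0 others. Simulated genes were drawn independently of each other, while the estimated correlation was 0.26 for cancer-testis antigens and 0.71 for interferon-stimulated genes. The simulation therefore does not show how often the preset correlation of 0.01 gives false list calls in these data.

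Alternatives covered the shRNA covariate, the treatment of lines, centring, scaling, quantile normalization, a robust prior, probes with values on all arrays, single probes, each array left out in turn, and other list tests. Fits on the arrays of 1 shRNA alone were added after seeing the data, as were the list tests of differences between lines and between shRNAs, with the preset and with an estimated correlation, the preset correlation on genes with all 6 values, the fits without shared ratios and the turned UHRF1 array. Scaling used the limma function normalizeMedianAbsValues, because the planned normalizeBetweenArrays gave no values on these ratios.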

Results

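The series measured how RNA levels changed in colorectal cancer cells after depletion of DNMT1 or of UHRF1. DLD1, HT29 and RKO cells each had 2 arrays, 1 for each of 2 shRNAs against DNMT1, and HCT116 cells had 1 array for UHRF1. Each array gave a log2 ratio of knockdown over control RNA of the same line, with the likely direction of the DNMT1 arrays read from DNMT1 itself. On the UHRF1 array it was read from the mean of 4 UHRF1 probes that disagree, so it is less certain there. The shRNA 49 arrays lacked a ratio for 205 (DLD1), 352 (HT29) and 329 (RKO) of 41000 probes. The shRNA 51 arrays lacked one for 2610, 5073 and 5075 probes, and the UHRF1 array for 1729. Ratios also spread more widely with shRNA 51, with interquartile ranges of 0.829, 0.778 and 0.968 against 0.558, 0.636 and 0.726 with shRNA 49 in DLD1, HT29 and RKO.

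DNMT1, read by 1 probe, lay below control on every DNMT1 array. Its level was 25.4% of control in DLD1 with shRNA 49 and 22.2% with shRNA 51, 23.8% and 52.8% in HT29, and 10.4% and 19.6% in RKO. The mean log2 ratio was -2.13 ± 0.27 (SE, n = 6), with an adjusted p of 0.0441 by limma. Here and below the SE of a mean is that of the fit, with the difference between the shRNAs taken out. On the UHRF1 array DNMT1 stood at 0.09. UHRF1 on that array averaged -1.16 over 4 probes that disagreed, at -3.10, -2.06, -0.18 and 0.68, where the label gives a knockdown efficiency of 60%. The de novo methyltransferases DNMT3A (0.31 ± 0.21, adjusted p = 0.621) and DNMT3B (0.73 ± 0.29, adjusted p = 0.409) and UHRF1 (0.27 ± 0.21, adjusted p = 0.674) did not pass the test under DNMT1 knockdown (SE, n = 6 for each).

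**Figure D1:**
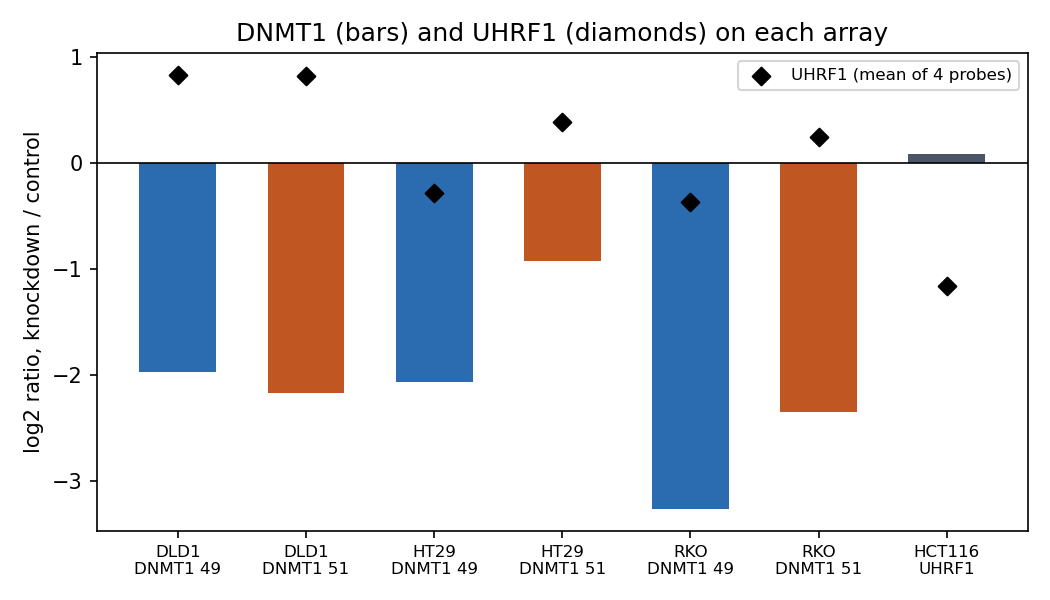
Log2 ratio of knockdown over control for DNMT1 (bars, blue for shRNA 49, orange for shRNA 51, grey for the UHRF1 array) and for UHRF1 (diamonds, mean of 4 probes), 1 array per bar. DNMT1 lies between -3.27 and -0.92 on the DNMT1 arrays and at 0.09 on the UHRF1 array, where UHRF1 lies at -1.16.

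The comparison over all 3 lines asks which genes change when DNMT1 is depleted, whatever the line. Among the genes that passed, VCX3A and VCX, X-linked genes expressed in male germ cells, had the highest means. They rose by 6.69 ± 0.32 and 6.40 ± 0.28 on the log2 scale (SE, n = 6, adjusted p = 0.000806 for both), or 103-fold and 84.5-fold. The tumour antigen gene CTAG1A, of the NY-ESO-1 family, rose 36.5-fold (5.19 ± 0.16, adjusted p = 0.000138). GAGE7 (5.21), PAGE2 (5.08), PAGE5 (4.93), VCX2 (4.74) and CT45A1 (4.63) rose too, each above 0 on all 6 arrays, with adjusted p between 0.000806 and 0.0138.

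In all, 67 genes rose and 3 fell among 17623 tested with limma, and 2005 had an unadjusted p under 0.05. All 67 were at least 2-fold higher on average, 41 had 1 sign on all 6 arrays, and 17 had a value on fewer than 6. The shRNA term takes the difference between the shRNAs out of the spread, so a gene raised with 1 shRNA alone can pass. The shRNA 49 mean was below 1.5-fold for 17 of the 67. The genes that fell were DNMT1, CRB2, a cell polarity gene (-1.19 ± 0.17, adjusted p = 0.0493), and NXNL2, a thioredoxin-like gene (-0.97 ± 0.13, adjusted p = 0.0443). The falls of CRB2 and NXNL2 are uncertain: they lay at -0.30, -0.20 and -0.04 and at -0.18, -0.18 and -0.10 with shRNA 49, and on 4 and 6 of the 6 arrays their only probe holds a ratio that other probes share exactly. With such ratios left out, an alternative added after seeing the data, neither could be tested. CASR, the calcium-sensing receptor, stood at -1.55 (adjusted p = 0.0565) and SUSD5, GLRA2, ARLNC1 and SOX9-AS1 at -1.61, -1.51, -1.50 and -1.46, none of which passed and which hold such ratios on 1 to 6 arrays. Near-identical copies of the VCX, GAGE, PAGE and CT45 genes were not told apart. The count of genes that rose depended on how the arrays were modelled: it was 10 without the shRNA covariate, 7 with the arrays of a line averaged first and 28 after quantile normalization, and leaving out 1 array gave between 8 (without RKO, shRNA 49) and 168 (without DLD1, shRNA 51). VCX3A, VCX, CTAG1A and CT45A1 passed under all 17 alternatives run for each of them, VCX2 under 15, GAGE7 and PAGE2 under 13, DNMT1 under 7, NXNL2 under 5 and CRB2 under 3. Of the genes named below, SPANXD and GTSF1 passed under 15, UCHL1 under 12, SOHLH1 and NEFH under 11, DAZL under 8, TDRD9 under 7 and KRT7 under 6 of the 17, CXCL11 under 7 of 16 and CCL20 under 2 of 15.

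Cancer-testis antigens, genes of the germ line that tumours can switch on, rose as a group. Their median log2 ratio was 2.03 over 40 tested members, of which 38 lay above 0, 17 rose over all genes tested and 32 rose when adjusted over the list alone. SPANXD, for example, rose by 3.99 ± 0.29 (adjusted p = 0.00625). The list passed with the preset correlation (adjusted p = 2.08e-108) and in the rotation test fry (adjusted p = 0.00495), but not with an estimated correlation (adjusted p = 0.234). Their medians on the 6 arrays were 0.33 and 2.96 in DLD1, 1.52 and 3.45 in HT29, and 0.65 and 4.27 in RKO, with shRNA 49 first in each pair. Without shared ratios, which other probes of an array hold exactly, they were 1.34 and 3.68, 2.09 and 3.89, and 2.15 and 5.29. Those medians rest on 19 and 34, 28 and 31, and 22 and 29 members, so they do not compare the same genes.

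Germline genes of meiosis and the piRNA pathway had a median of 0.63 over 42 members. The list passed with the preset correlation (adjusted p = 8.53e-15), but not with an estimated correlation (adjusted p = 0.535) or in the rotation test (adjusted p = 0.103). The smallest p-values belonged to GTSF1 and TDRD9, which act in piRNA silencing, the germ cell transcription factor SOHLH1 and the germ cell RNA-binding protein DAZL. They rose by 3.72, 2.53, 2.98 and 4.57, with adjusted p of 0.00615, 0.0469, 0.0207 and 0.0469. The 2 probes of SOHLH1 disagree, at 1.56 (adjusted p = 0.223) and 4.40 (adjusted p = 0.00329), so its size is uncertain. TDRD9 and DAZL were below 0 in DLD1 with shRNA 49, at -0.34 and -0.46, but both are ratios that other probes share. DAZL could not be tested without shared ratios. Of the list, 4 members passed over all genes and 15 when adjusted over the list alone.

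Inflammatory genes under NF-kB control had a median of 0.64, with all 22 members above 0. On the arrays the median was -0.094, 0.14 and -0.026 with shRNA 49 and 0.51, 2.29 and 0.48 with shRNA 51 in DLD1, HT29 and RKO. The chemokine gene CCL20 rose by 2.07 ± 0.25 (SE, n = 5, adjusted p = 0.0488), and 6 members passed when adjusted over the list alone. That call of CCL20 ended under 13 of 15 alternatives, 1 of them the test of its only probe (adjusted p = 0.0523), and without shared ratios it could not be tested. CCL20 lay at 0.68, -0.13 and -0.57 with shRNA 49, and at 4.39 in HT29 and 3.78 in RKO with shRNA 51. LTB (1.28), IL32 (1.27) and RELB (0.74) did not pass over all genes. The list's adjusted p was 2.64e-06 with the preset correlation, and the adjusted p was 0.578 with an estimated correlation. Interferon-stimulated genes had a median of 0.46 (adjusted p = 0.0185, and adjusted p = 0.742 with an estimated correlation), with CXCL11 the 1 of 43 members to rise over all genes (2.03 ± 0.24, adjusted p = 0.0346; 1.98 ± 0.32, adjusted p = 0.0831 without shared ratios, where the size stayed and the spread grew) and 3 when adjusted over the list alone. Their median was 3.14 in HT29 with shRNA 51 and between -0.79 and 0.27 on the other DNMT1 arrays, and without that HT29 array the all-lines median was -0.083. With the shRNA 49 arrays alone it was -0.25, and the list was then called lower (adjusted p = 0.042). Antigen presentation genes, among them CD74 (1.35) and HLA-DPB1 (0.84), had a median of 0.33 and 0 of 22 members passed (list adjusted p = 0.0447, and adjusted p = 0.681 with an estimated correlation); with shRNA 49 alone the median was -0.022.

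Metallothioneins, small metal-binding proteins, had a median of 0.84. No member passed over all genes and 7 of 11 rose when adjusted over the list alone, while MT2A (1.29) and MT1X (0.90) stood at an adjusted p of 0.282 and 0.293. Their median lay at 0.02, -0.69 and -0.36 with shRNA 49 and at 1.36, 1.73 and 3.05 with shRNA 51, so the direction turned with shRNA 49 alone (-0.38). The list's adjusted p was 0.000162, with an adjusted p of 0.578 for an estimated correlation. Probes of MT1H, MT1L and MT1X read nearly alike, between 2.87 and 3.51 in RKO with shRNA 51. Whether such members share hybridising RNA was not checked, so 7 of 11 may overstate the number of separate genes. Among genes often hypermethylated at their promoters in colorectal cancer, UCHL1, a ubiquitin hydrolase, rose by 4.60 ± 0.37 (adjusted p = 0.00983) as 1 of 53 members, with 3 when adjusted over the list alone. The chromatin remodeller HLTF (2.13, adjusted p = 0.172) and the Wnt antagonist DKK3 (0.75, adjusted p = 0.215) did not pass. The list's median was 0.13 (adjusted p = 0.00316, and adjusted p = 0.535 with an estimated correlation). With shRNA 49 alone it was 0.058 and did not pass (adjusted p = 0.760), with shRNA 51 alone 0.33. Mesenchymal genes (median 0.42, adjusted p = 0.0360) and imprinted genes (0.26, adjusted p = 0.0360) also passed as lists, with 0 members past the threshold in each, and their adjusted p was 0.581 and 0.742 with an estimated correlation. The array medians averaged 0.11 with shRNA 49 and 0.39 with shRNA 51 for mesenchymal genes, and 0.022 and 0.38 for imprinted genes. SGCE (1.99) and H19 (2.03), both imprinted, had adjusted p of 0.182 and 0.343.

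Lower as groups were ribosomal protein genes and genes of hypoxia and glycolysis. Of 35 ribosomal protein genes 3 lay above 0, with a median of -0.15 (list adjusted p = 5.41e-05, and adjusted p = 0.581 with an estimated correlation), and RPS2 (-0.52) and RPL3 (-0.49) did not pass alone. The hypoxia list had a median of -0.19 (adjusted p = 0.0218, and adjusted p = 0.670 with an estimated correlation), with GAPDH at -0.44 and PFKFB4 at -0.66, and stood at 0.063 with shRNA 49 alone. BNIP3, a mitochondrial receptor gene on the same list, went the other way at 2.53 and rose when adjusted over the list alone, though not over all genes (adjusted p = 0.153). It lay at -0.04, 0.02 and 0.45 with shRNA 49, all ratios that other probes share, and at 4.69, 2.93 and 7.12 with shRNA 51.

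The remaining lists gave fewer calls. Markers of fibroblasts and endothelium, which a pure line should lack, had a median of 0.27 (adjusted p = 0.0447, and adjusted p = 0.581 with an estimated correlation), with PECAM1 at 1.32 and VWF at 0.79, neither past the threshold, and 1 of 18 members when adjusted over the list alone. Markers of haematopoietic cells had a median of 0.16 (adjusted p = 0.0678) and those of neurons and glia -0.07 (adjusted p = 0.329), although the test statistic of the latter pointed up and NEFH, a neurofilament gene, rose by 3.18 ± 0.28 (adjusted p = 0.0138). KRT7, a simple epithelial keratin, rose by 4.29 ± 0.58 (adjusted p = 0.0482) in a list of epithelial genes that did not pass (median 0.07, adjusted p = 0.337). Mitosis genes (-0.07, adjusted p = 0.0908), unfolded protein response genes (-0.23, 0.0908), S phase genes (0.12, 0.329), oxidative phosphorylation (0.01, 0.329), HOX genes (0.07, 0.547), Wnt targets (0.24, 0.577), other DNA methylation factors (0.13, 0.669), differentiated colon markers (0.23, 0.669), cholesterol synthesis (0.04, 0.868), p53 targets (0.04, 0.875) and immediate early genes (0.15, 0.972) did not pass. The oxidative phosphorylation and p53 medians lay above 0 while their test statistics pointed down. Of the 26 lists 10 were called higher and 2 lower with the preset correlation, and 0 with an estimated correlation. That test used only the 15793 genes with a value on all 6 arrays, on which the preset correlation called 7 higher and 2 lower. With few residual degrees of freedom it may have had little power. The estimated correlations lay above 0.01 for most lists, up to 0.71 for interferon-stimulated genes, so the calls made under the preset alone may be too many. The smallest unadjusted p with an estimated correlation, that of cancer-testis antigens, was 0.00900. The rotation test called cancer-testis antigens alone.

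**Figure D2:**
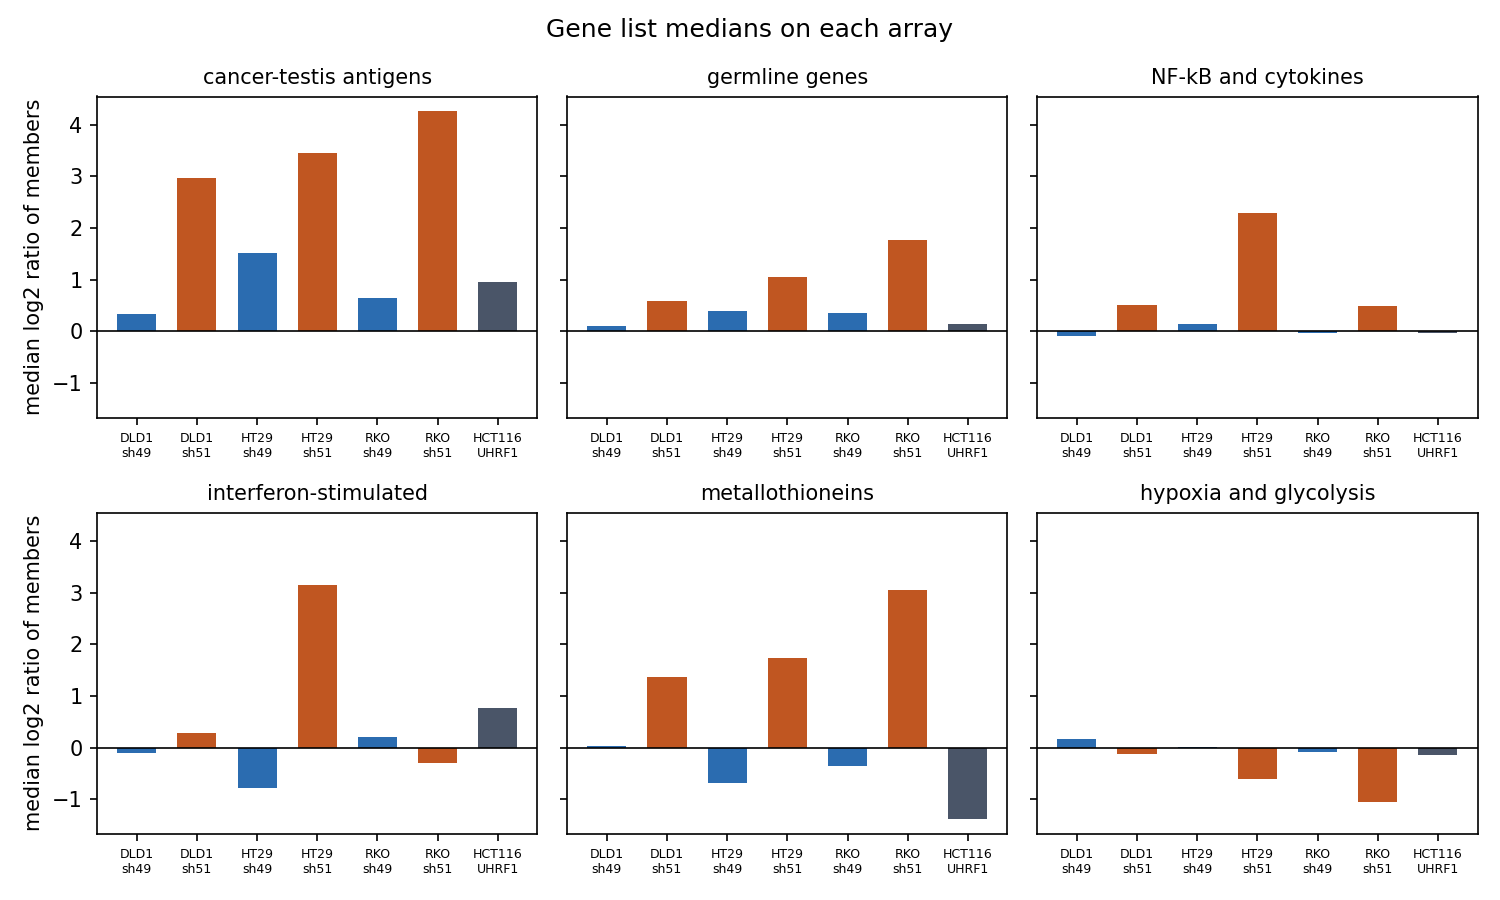
Median log2 ratio of the members of 6 gene lists (knockdown over control) on each of the 7 arrays, 1 bar per array, blue for shRNA 49, orange for shRNA 51 and grey for the UHRF1 array. Cancer-testis antigens reach 4.27 in RKO with shRNA 51 and 0.65 with shRNA 49, and interferon-stimulated genes reach 3.14 in HT29 with shRNA 51.

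Within single lines fewer genes passed. VCX3A, VCX and CTAG1A rose in all 3 lines: VCX3A by 5.99 ± 0.30 in DLD1, 6.42 ± 0.30 in HT29 and 7.65 ± 0.30 in RKO (SE, n = 2 arrays per line, spread shared over the lines), with adjusted p of 0.0381, 0.0365 and 0.0250. FSTL1, a secreted glycoprotein gene, rose most in DLD1, by 6.76 ± 0.28 (adjusted p = 0.0381). In RKO the intermediate filament gene VIM rose by 5.60 ± 0.28 (adjusted p = 0.0362) and VCX2 by 5.54 ± 0.33 (adjusted p = 0.0446). In total 4 genes rose in DLD1, 3 in HT29 and 8 in RKO, none fell, and 1551, 1416 and 2201 had an unadjusted p under 0.05 in limma. Each pair of lines shared 3 genes, but the lines share 1 spread per gene and the shRNA term in this fit, so their calls are not independent. In simulated data with spread shared by the arrays of a line, 20 of 117 such calls were false. The counts were 0 in every line without the shRNA covariate and 35, 34 and 24 after quantile normalization, and leaving out 1 array gave between 0 and 14 genes in DLD1, 0 in HT29 and between 0 and 45 in RKO.

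Some genes stood far apart between the lines, but none passed the test of the difference. In DLD1 the peptidase gene KLK11 averaged 4.17, the secreted lectin gene ZG16B 4.26 and the developmental transcription factor SIX2 3.94, against -0.63 to 0.25 in the other lines. LINC02381 (4.50), C1QTNF9B (3.23) and HEG1 (1.81) were highest in HT29. S100A10 (4.91), VIM (5.60) and CRIP1 (3.45) were highest in RKO, where S100A10 rose within the line (adjusted p = 0.0431). Ratios that other probes share make several of these contrasts uncertain. They stand for KLK11 in DLD1 with shRNA 51, and for KLK11 and ZG16B on both RKO arrays. LINC02381 and C1QTNF9B hold them on both arrays of DLD1 and of RKO. SIX2 holds them in HT29 and RKO with shRNA 51, and VIM in DLD1 and HT29 with shRNA 49. The limma F test called 0 genes, with a smallest adjusted p of 0.646, and 1137 genes had an unadjusted p under 0.05. The pairwise differences called 0 genes too. With 2 arrays per line, the simulated test recovered 62.1% of genes changed by 4 in 1 line and 1.49% of those changed by 2.

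No single gene passed the test between the 2 shRNAs. Of the 67 genes that rose over all lines, 66 (98.5%) had a higher mean with shRNA 51 than with shRNA 49, against 57.2% of all 17623 tested genes and 92.4% of the 616 others with a mean at least 2-fold higher. Choosing genes by a high mean favours the arrays with wider ratios, so this count is no test of the shRNAs. All 67 were at least 2-fold higher on the shRNA 51 mean and 38 on the shRNA 49 mean. Their median was 1.24 with shRNA 49 and 4.04 with shRNA 51. DAZL (5.99), UCHL1 (4.39), CCL20 (4.43) and CXCL11 (3.81) had wide differences of shRNA 51 minus shRNA 49, with adjusted p of 0.313 each. Of the 26 lists 11 differed with the preset correlation, but 0 with an estimated correlation (smallest adjusted p = 0.565), a test added after seeing the data on the genes with all 6 values, where the preset correlation gave 13. The test with an estimated correlation has few residual degrees of freedom, so its 0 decides little. The calls made under the preset alone are uncertain too. List differences here are medians of the members' own differences. With the preset correlation cancer-testis antigens differed by 2.42 (adjusted p = 6.75e-44), metallothioneins by 2.25 (6.85e-11), germline genes by 1.04 (1.34e-08), interferon-stimulated genes by 1.40 (0.000944) and NF-kB genes by 0.86 (1.34e-05), while cholesterol synthesis genes differed by -0.72 (9.81e-05) and hypoxia genes by -0.52 (0.000576). The others were promoter-hypermethylated genes (0.38, adjusted p = 0.00147), antigen presentation (0.44, 0.0158), S phase (-0.21, 0.0105) and mitosis (-0.18, 0.0284). The limma contrast called 0 genes with a smallest adjusted p of 0.231, and 1982 had an unadjusted p under 0.05. shRNA and dye orientation are the same split, so these values measure both. Ratios that other probes share exactly make up 50.8%, 56.5% and 44.6% of those past 2-fold on the shRNA 51 arrays of DLD1, HT29 and RKO, against 31.3%, 19.9% and 22.7% with shRNA 49. Without them, the ratio of cancer-testis medians fell from 4.26 to 2.3. That fall compares unlike members, 19, 28 and 22 with shRNA 49 and 34, 31 and 29 with shRNA 51 in DLD1, HT29 and RKO.

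**Figure D3:**
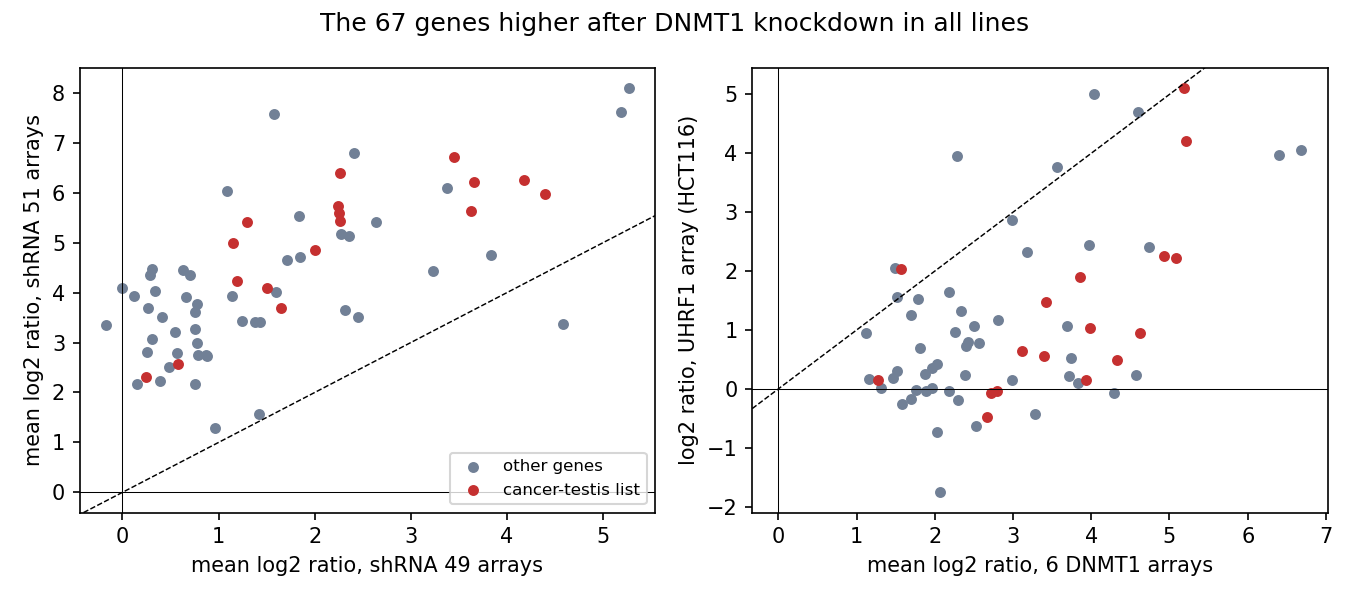
Left, mean log2 ratio of the 67 genes that rose over all lines on the 3 shRNA 49 arrays (horizontal) and the 3 shRNA 51 arrays (vertical). Right, their mean over the 6 DNMT1 arrays (horizontal) and their log2 ratio on the UHRF1 array (vertical); red points are on the cancer-testis list, dashed lines mark equal values, and 66 of 67 genes lie above the line at left.

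UHRF1 knockdown in HCT116 cells, with 1 array and no replicate, had a cancer-testis antigen gene and UCHL1 among its highest ratios. GALNT15, a glycosyltransferase gene, was highest at 6.69, followed by the cadherin gene CDH26 (5.32), CTAG1A (5.11), COX7B2 (5.01), SPARC (4.93), LGSN (4.82), UCHL1 (4.70) and ATP1B4 (4.63). The lowest were RAET1E-AS1 (-3.20), MPDZ (-2.75), C1QTNF5 (-2.65), PYDC1 (-2.59), PROM1 (-2.56), SULF2 (-2.53), CT75 (-2.46) and KCNIP1 (-2.46). For ATP1B4, MPDZ, PROM1, CT75 and KCNIP1 a probe holds a ratio that other probes of the array share exactly, so their values and ranks are uncertain. Such shared ratios make up 44% of all ratios on this array and 68.6% of those past 2-fold. Of 17366 genes with a value 687 (3.96%) were at least 2-fold higher and 357 (2.06%) at least 2-fold lower. With shared ratios left out it was 388 and 196 of 12004.

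Among the lists, cancer-testis antigens had a median of 0.95 on the UHRF1 array, above all 10000 random lists, and 18 of 38 members were at least 2-fold higher, such as GAGE7 (4.20) and PAGE1 (3.76). Interferon-stimulated genes had a median of 0.77, also above all random lists, with 16 of 42 members at least 2-fold higher, among them IFI27 (3.20), IFI44 (2.25) and IFITM1 (2.24). Metallothioneins had a median of -1.39, below all random lists, with 7 of 11 members at least 2-fold lower, such as MT1M (-1.82) and MT2A (-1.59). Metallothionein members may not be separate readings, which random lists do not reproduce. Epithelial genes (-0.31, with LAMB3 at -1.43 and CDH1, E-cadherin, at -1.39), HOX genes (-0.32, with HOXC13 at -1.59), cholesterol synthesis genes (-0.33, with MSMO1 at -1.22) and hypoxia genes (-0.15, with P4HA2 at -0.91) lay below the central 95% of random lists. The other lists lay inside it. With shared ratios left out these 7 lists stayed outside on the same side, and germline genes lay above the range too (0.443). The cancer-testis median was then 1.57, with 17 of 30 members at least 2-fold higher. These values describe 1 array and have no test, and if that array runs the other way every sign turns.

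Genes that rose with DNMT1 knockdown tended to be higher on the UHRF1 array, in the direction taken as likely. Of the 67, 53 (79.1%) lay above 0, 27 (40.3%) were at least 2-fold higher and 1 was at least 2-fold lower, CCL20 at -1.76, a shared ratio. Without shared ratios 26 of 45 were at least 2-fold higher and 0 lower, with a median of 1.25. If the UHRF1 array runs the other way, 27 were at least 2-fold lower and 1 higher. The median of all 67, 0.70, was above all 10000 random lists. The time after knockdown may differ between the UHRF1 and DNMT1 arrays, since only the UHRF1 title carries d14. CTAG1A stood at 5.19 and 5.11 and UCHL1 at 4.60 and 4.70, though UCHL1 ran from 0.82 to 7.22 on the DNMT1 arrays. KRT7 stood at 4.29 and -0.07 and DAZL at 4.57 and 0.23, where both values on the UHRF1 array are shared ratios and uncertain. Across all genes, which are not independent replicates, the correlation of the UHRF1 array with the mean of the DNMT1 arrays was weak (Pearson r = 0.203, Spearman rho = 0.107; r = -0.203 with the array turned). It was 0.0875 with the shRNA 49 arrays and 0.211 with the shRNA 51 arrays, which share the dye orientation of the UHRF1 array. Among the DNMT1 arrays the mean Pearson r was 0.271 between the arrays of a line, 0.242 between lines with the same shRNA and 0.0965 between lines with different shRNAs; where arrays of a line share a control, unchanged samples alone would give up to 0.5.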

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

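The tests in this part were chosen after the result was seen, except the dye slope of the cancer-testis genes and the splits of the arrays. How the sign assignments, the dye slope, the DNMT1 difference, the scaled ratio, the blood cell markers and the genes of opposite sign are judged was changed after their values were known.

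Several gene groups stood apart between the 3 lines, by a test of the difference over lists (78 differences, 24 past the threshold, in 14 lists; preset correlation, 2 arrays per line). With an estimated correlation, added after seeing the data, 0 of the 78 passed (smallest adjusted p = 0.7), on genes with a value on all 6 arrays, where the preset gave 25. With few residual degrees of freedom, the test with an estimated correlation may have had little power, so its 0 decides little. The differences below were called only under the preset and are uncertain. Each difference is the median of the members' own differences, so it need not equal the difference of 2 list medians. Immediate early genes stood at 0.63 in DLD1 and -0.55 in HT29, with a median difference of 1.23 (adjusted p = 7.67e-12), and RKO at 0.49. Epithelial junction and keratin genes were 0.940 higher in DLD1 than in RKO. Cancer-testis antigens were lower in DLD1 than in HT29 by a difference of -0.769, and germline genes lower in DLD1 than in RKO by a difference of -0.584. S phase genes and mitosis genes were lower in DLD1 than in HT29, with differences of -0.665 and -0.358. Hypoxia genes differed by 0.412 between DLD1 and RKO. HT29 exceeded RKO in NF-kB genes by 0.639 and in interferon-stimulated genes by 1.39, and DLD1 minus HT29 was -0.860 for antigen presentation. In HT29 these rest on the shRNA 51 array, with medians of 2.29, 3.14 and 1.58 for these lists against 0.14, -0.79 and -0.039 with shRNA 49. Smaller differences were -0.337 for p53 targets and -0.0907 for promoter-hypermethylated genes (HT29 minus RKO), 0.328 for imprinted genes (DLD1 minus HT29) and 0.175 for differentiated colon markers (DLD1 minus RKO). Among probes without a single gene name, which no comparison above used, 3 of 10175 rose over all lines and 0 fell.

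The 67 genes that rose and the 3 that fell were set against chance. Of 32 ways to assign signs to the 6 arrays, 1, the real one, called as many as 70 genes, and the highest other called 4. That other one turned the signs of all shRNA 51 arrays. In the rest the turned signs move any true change and any shRNA difference into the spread. This lowers their counts, so they are no fair measure of chance. Fewer than 5 percent of assignments was the mark set beforehand, but it took the 6 arrays as independent, and arrays of a line may share a control. With lines kept together there are 4 assignments, too few for a share under 0.05; the real one called 70 genes and the highest other 0. For the 2 shRNAs, the 10 splits of 3 against 3 arrays are too few for a share under 0.05; the real split called 0 genes, the highest other 0, and all 10 called as many.

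Cancer-testis antigens had higher medians with shRNA 51 than with shRNA 49, a difference that passed with the preset correlation (adjusted p = 6.75e-44) and not with an estimated correlation (adjusted p = 0.565). A deeper loss of DNMT1 stays open, since DNMT1 was read by 1 probe and as RNA only. It stood higher with shRNA 51 by 0.623 ± 0.372 (SE, limma p adjusted over all genes = 0.562). DNMT1 was higher with shRNA 51 in HT29 (-0.92 against -2.07) and RKO (-2.35 against -3.27), against a deeper loss there. In DLD1 it was lower (-2.17 against -1.97). Wider ratios on the shRNA 51 arrays stay open as a cause. After scaling every array to 1 spread the list median was 3.22 times that with shRNA 49, against 4.26 times before, but without ratios that several probes share it was 2.3 times before and 1.73 times after scaling. The values without shared ratios compare unlike members, 19 to 28 per array with shRNA 49 and 29 to 34 with shRNA 51, so they decide little. A dye bias of these genes stays open: the slope of the UHRF1 array on their orientation term was -0.696 (bootstrap 95% interval -1.68 to 0.458), where a dye bias would give about 1. The mark set beforehand against it, an upper end below 0.5, was met. That mark was wrong for this design, since the interval resamples genes and leaves out the spread between arrays, and the slope rests on 1 array of another line and target. If that array runs the other way, the slope is 0.696 (-0.458 to 1.68). The shRNAs themselves and the dye cannot be told apart in these arrays, and a biological difference between the shRNAs remains untested.

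Interferon-stimulated genes had a median of 3.14 in HT29 with shRNA 51. A dye bias is argued against as the whole cause, because the other shRNA 51 arrays, of the same orientation, gave at most 0.275. The UHRF1 array, also of that orientation, gave 0.77 in the direction taken as likely, above those arrays but far below 3.14, and -0.77 if it runs the other way, so a smaller dye share is left open. RNA from blood cells is argued against as the whole cause by the median of 19 haematopoietic markers on the HT29 array, 0.162 (SD 0.844), far below the interferon median of 3.14 and the mark of 1.57. Leaving out shared ratios gave a marker median of 0.25 over 12 markers. PTPRC stood at 0.456, while HBB (2.48), CSF1R (1.56), TYROBP (1.21) and CD3D (1.205) were at least 2-fold higher and CORO1A (-1.199) at least 2-fold lower, named after their values were seen. With shared ratios left out HBB stood at 1.16, and PTPRC and CD3D had no value. A response of that culture to its shRNA or handling may remain, and was not tested.

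A few genes had opposite signs with the shRNAs. C1QTNF5, RAET1E-AS1, LIN28A and BAALC-AS2, found after their values were seen, were more than 2-fold higher on all 3 shRNA 49 arrays and more than 2-fold lower on all 3 shRNA 51 arrays. All 4 of these 4 genes were also lower on the UHRF1 array, at -2.65, -3.20, -1.72 and -1.28, as a gene-specific dye bias would give, in a different line and for a different target. If that array runs the other way, 0 of the 4 are lower, so this stays open. Over 11721 genes with a mean response near 0, the correlation of the orientation term with the UHRF1 array was 0.0882, below the 0.1 set as its mark (-0.0882 with the array turned), and 1 array leaves open how far such a bias reaches.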

How the results depend on the processing

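The fits on 1 shRNA alone and the list differences with an estimated correlation (0 called for lines and 0 for shRNAs) were added after seeing the data, as were the fits without ratios that several probes of an array share exactly, the preset correlation on genes with all 6 values, the turned UHRF1 array and 2 of the X chromosome tests; all other alternatives were planned. The replicate number here names the shRNA, so the shRNA covariate of the main fit is a replicate block, and the fit without it has none. The 2 arrays of a line are paired in the fits with lines as fixed coefficients. A filter on dim probes was not run, since signal over background was not used here. VCX3A, VCX, CTAG1A and CT45A1 passed under all 17 alternatives. The cause of the changes below was not tested. Over all lines the counts of genes higher and lower were 10 and 0 without the shRNA covariate (no replicate block), 7 and 0 with 3 line means, 28 and 0 after quantile normalization, 5 and 0 with shRNA 49 alone, and 19 and 0 with shRNA 51 alone, where 18 of the 19 were among the 67. Genes lower were 1 with lines as fixed coefficients (67 higher, 40 shared), 1 after scaling, 1 with a robust prior, 6 with complete probes and 5 per probe. Without shared ratios 65 were higher and 3 lower of 11485, with 24 and 2 of them not called in the main fit. Of the 67 risen genes 43 could be tested and 41 passed. Of the 3 that fell only DNMT1 could be tested, and it passed; the other 2 lower were PRSS1 (-1.49) and TUB (-1.02), named after their values were seen. Leaving out 1 array gave 8 to 168 higher and 0 to 38 lower; it rose to 168, 105 and 135 without the shRNA 51 array of DLD1, HT29 or RKO, and fell to 12, 18 and 8 without that of shRNA 49. Within DLD1, HT29 and RKO the counts were 0, 0 and 0 without the covariate, 15, 19 and 12 after scaling, 35, 34 and 24 after quantile normalization, 15, 23 and 46 with complete probes, and 0, 3 and 14 per probe; leaving out 1 array gave 0 to 14, 0 and 0 to 45. Counts for line differences and for the shRNA contrast stayed at 0 under every alternative run. Lists higher and lower were 0 and 0 with an estimated correlation and 1 and 0 in the rotation test, both on genes with all 6 values, where the preset correlation gave 7 and 2. They were 5 and 2 with shRNA 49 alone and 9 and 5 with shRNA 51 alone; 1 was lower after scaling and 1 after quantile normalization, and leaving out 1 array gave 5 to 10 higher and 1 to 3 lower. On the UHRF1 array the counts higher and lower were 1077 and 647 per probe and 1776 and 1129 at 1.5-fold. Its correlation was 0.538 over the risen and fallen genes, 0.0875 with shRNA 49, 0.107 with DLD1 and 0.141 with RKO.

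Among single genes, 1948 of 2102 alternatives kept direction and side of the threshold, 121 lost the call, 14 gained it and 19 changed sign; among lists these were 383 of 494, 62, 15 and 34. Signs turned with shRNA 49 alone for HLA-DPA1 -0.042, FDPS 0.090, CLCA1 0.69, TJP1 -0.048, COL1A2 -0.031, TYROBP -0.083, MT2A -0.14, MT1X -0.41, MT1H -0.35, CCL20 -0.0054, SDHA 0.069, ATP5F1B 0.071, APCDD1 -0.23 and HEG1 0.025, and for the lists antigen presentation -0.022, hypoxia 0.063, immediate early -0.043, interferon -0.25 and metallothioneins -0.38. With shRNA 51 alone medians turned for cholesterol synthesis -0.36, HOX -0.021 and Wnt targets -0.12. Only the direction of the test turned, and not the median, for colon markers with shRNA 49 alone (0.037) and S phase with shRNA 51 alone (0.027). HEG1 was 0.068 after scaling and 0.030 after quantile normalization, and ASCL2 -0.070 per probe. By the direction of its test, the immediate early list turned with 3 line means (0.15), scaling (0.11) and quantile normalization (0.12), HOX genes with an estimated correlation and with complete probes (-4.64e-05 in both, since both left out genes without all 6 values), Wnt targets with complete probes (0.25), and p53 targets with fixed lines and in the rotation test (0.038 in both). Leaving out 1 array turned the direction, by the list test or the value of the gene, in at least 1 run for each of the following, whose printed medians need not change sign: HEG1 -0.54 to 0.50, interferon -0.083 to 0.78, cholesterol -0.039 to 0.23, epithelial -0.18 to 0.24, S phase 0.031 to 0.22, p53 -0.0022 to 0.10, colon markers 0.15 to 0.23, DNA methylation factors 0.053 to 0.18 and immediate early 0.0043 to 0.30.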

Other observations

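The tests of the X chromosome and of the shRNA 49 genes were set before their results were seen, that of neighbouring genes after the called genes had been read. The X chromosome tests by family outside the list and without the VCX genes, and how they are judged together, were added after seeing the data. How the shRNA 49 genes and the neighbouring pairs are judged was changed after their values were known.

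Genes that rose under DNMT1 knockdown lay on the X chromosome more often than other genes. Of 66 risen genes with a known chromosome 26 (39.4%) were X-linked, against 3.65% of all tested genes (Fisher's exact p = 1.06e-20, odds ratio 17.8). Counting genes that share a symbol stem once, 14 of 51 families (27.5%) were X-linked against 6.84% of all, with a Fisher's exact p of 4.86e-06, so near-identical copies are unlikely to account for all of it. Without the families of the cancer-testis list, 6 of 46 were X-linked (13% against 3.35%, Fisher's exact p = 0.00413, odds ratio 4.36). They were VCX3A, VCX, VCX2, CCNB3, PNMA5 and RHOXF2B, the last 3 named after their values were seen. This passes the mark set beforehand against the cancer-testis families as the whole cause, but the mark counted the near-identical VCX copies as separate genes. With 1 gene per family 4 of 41 were X-linked (9.76% against 6.61%, Fisher's exact p = 0.345), and without the 4 risen genes of the VCX family, 3 of them X-linked, it was 3 of 42 (7.14% against 3.33%, Fisher's exact p = 0.164, odds ratio 2.24). Whether the X-linked share extends beyond these families stays open.

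Risen genes were also tested for clustering along chromosomes, among the measured genes. There were 6 neighbouring pairs, all on X, such as PAGE2B with PAGE2, CT45A1 with CT45A5 and CSAG1 with MAGEA12, where the highest of 10000 random draws gave 4. Within 1 family lay 3 pairs, and the other 3 lay in 1 run of MAGEA and CSAG copies. Counting only pairs between different families, random draws gave at most 4 (permutation p = 0.0018), a count added after seeing the data. Pairs of genes without other risen copies numbered 0. Draws of single genes are no fair measure for copies that lie together, so clustering along chromosomes beyond these families stays open.

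The 100 genes with the highest mean on the shRNA 49 arrays had a median of 0.509 on the UHRF1 array, above all 10000 random lists, and 37 were at least 2-fold higher there. The shRNA 49 arrays carry the opposite dye orientation to the UHRF1 array, so a dye bias would have turned these genes the other way if the UHRF1 array reads knockdown over control. This met the mark set beforehand for a shared response to loss of DNMT1 or UHRF1, but the mark took that direction as settled. If the array runs the other way, the median is -0.509, as a dye bias would give, so both stay open, from 1 UHRF1 array in a line of its own.

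DNMT1 levels and cancer-testis medians, with shRNA 49 first, were 25.4% with 0.33 and 22.2% with 2.96 in DLD1, 23.8% with 1.52 and 52.8% with 3.45 in HT29, and 10.4% with 0.65 and 19.6% with 4.27 in RKO. Without ratios that several probes share, the medians with shRNA 49 were 1.34, 2.09 and 2.15 and with shRNA 51 3.68, 3.89 and 5.29, over fewer members that differ between arrays. In DLD1 the array with less DNMT1 had the higher median, in HT29 and RKO the array with more. shRNA and dye differ between the arrays too, and arrays of a line are not independent, so no correlation was computed.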
